A study of Mus musculus with 18 samples.

How the data were processed

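Genomic DNA from mouse cells was profiled by RRBS in 12 libraries. WT and K36M MEFs (d0), reprogramming intermediates at d4 and d8, and passaged iPSCs were sampled, with 1 library per genotype at d0 and in iPSCs and 2 per genotype at d4 and at d8. Per the labels, libraries were made from 100 ng of DNA with a NuGen Ovation RRBS Methyl-Seq kit and sequenced as 100-bp single-end reads on a NovaSeq instrument. Per the submitters' processing notes, reads were trimmed with cutadapt and aligned with BSMAP to mm9; versions, the caller of methylation and its filters are not given in the sources used here. The labels also name 6 whole-genome bisulfite samples in 3 groups (WT, K36M and K36M with DMOG at d4), which were not analysed here.

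The deposited tables give, for each CpG and library, whole-number counts of methylated reads and of all reads over the site, with both strands summed, per the file headers. They also hold the fraction of methylated reads, which the authors rounded to 3 decimals; it differed from the ratio of the counts by at most 0.0005, so the counts were used throughout. All listed positions (100%) fell on a CpG of the NCBIM37 (mm9) sequence, and chromosome names and lengths matched. Gene models were taken from the GENCODE vM1 annotation of that build. All coordinates are mm9 and count from 1.

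CpGs were used where every library concerned had at least 10 reads (5 and 20 as alternatives). Each library's mean methylation was the unweighted mean over the 2411565 CpGs that met this in all 12 libraries. Counts were summed over tiles of 1 kb with at least 3 such CpGs (227787 tiles over the 8 d4 and d8 libraries, 223636 over all 12) and over promoters, 1 kb either side of a start, with 1 start per gene, the one with the most measured CpGs (18544 promoters, median of 44 CpGs and 3072 reads per library). Tiles had a median of 5 CpGs and 308 reads per library. Promoters were limited to protein-coding, processed-transcript and lincRNA genes, a choice made after the files were seen; all gene types are an added alternative. Tiles within 1 kb of a start were promoter tiles, others inside a gene were gene body tiles and the rest intergenic.

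Differences between groups were tested with edgeR's quasi-likelihood test on the methylated and unmethylated counts of the 8 d4 and d8 libraries in one fit, with a coefficient per group and 1 common negative binomial dispersion, a value chosen after the files were seen (dispersion 0 is an added alternative). A call needed a Benjamini-Hochberg adjusted p under 0.05 and a difference of group means of at least 10 percentage points. Adjusted p-values given for genes come from this test, are two-sided and are adjusted over all 18544 promoters unless stated. Means and classes of tiles were compared by exact two-sided permutation of the genotype labels within each day (36 arrangements, smallest p = 0.0556). Stages with 1 library per genotype were not tested on their own; they enter 1 alternative, which permutes genotypes within all 4 stages. Counting intervals (95%, normal approximation to binomial counting error summed over CpGs) cover counting error only, as PCR copies are not independent molecules. The labels do not say whether replicates are separate cultures or animals, so p-values measure the spread between these libraries, which may be technical. Tests at d4 and d8 rest on 2 libraries per group; the chance that all 4 libraries of a day separate by genotype is 33.3% with no effect.

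Before the data were examined, 13 lists of 20 genes were fixed: pluripotency and early reprogramming, germline, epithelial, mesenchymal and fibroblast, TGF-beta signalling, imprinted, DNA and H3K36 methylation enzymes, Hox, trophectoderm and placenta, and 4 lists of other cell types (blood, endothelial, neural and neural crest, skeletal and smooth muscle). Of 260 genes, 257 were in the annotation, 4 of them under an older symbol; this matching was done after the list tests had first been seen, and 3 genes were not in it (Rhox5, Kcnq1ot1 and Peg13). Lists were tested with limma's camera on log2((methylated + 1)/(unmethylated + 1)), preset correlation 0.01, two-sided, adjusted over 13 lists and 2 days; 12 of the 26 passed 0.05 and 0 with an estimated correlation. camera asks whether a list differs from the other promoters. Genes were named by a rule fixed in advance: on each day the 10 largest losses and 5 largest gains among called promoters with no overlap between genotypes, and up to 4 members per list with the largest difference averaged over both days. Other list members are named only as called or not, and 2 promoters that the rule names are not reported here.

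The fits were tested on simulated counts with 200 changed features. Each feature and library was drawn independently, with no shift shared by a whole library. Real replicates did shift, by a mean over tiles of 1.23 points in WT d4 and -0.98 in K36M d8 (replicate 2 minus 1). The false calls given here therefore do not cover such shifts. In 20000 tiles at d4, edgeR called 90 of 100 tiles changed by 20 points and 19 of 100 changed by 10 points, with 2 false calls; limma called 42 and 0. In 18544 promoters at d4, edgeR called 93 and 20 of 100, with 0 false calls; limma called 19 and 2. Replicates were compared before averaging: their squared differences over tiles were 1.29 to 1.66 times the counting variance, so 0 pairs agreed within counting noise. Equal replicate numbers did not pair libraries across groups (correlations of deviations -0.0777 to 0.0130).

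Alternatives covered the coverage minimum, the deepest 0.1% of CpGs left out, 500-bp tiles and promoters, at least 5 CpGs per tile, calls at 20 points or on the adjusted p alone, limma on log ratios with and without centring each library, a replicate block, autosomes, pooled reads, each library's own CpGs, and each of the 8 libraries left out in turn. Tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and limma 3.58.1.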

Results

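Reduced representation bisulfite sequencing (RRBS), which enriches CpG-rich fragments by restriction digestion and reads each CpG as methylated or unmethylated, was carried out on 12 libraries of mouse cells. The cells were embryonic fibroblasts (MEFs, d0), reprogramming intermediates at d4 and d8 in AGi medium, and induced pluripotent stem cells (iPSCs) that had been passaged in S/L without doxycycline. Each stage was sampled in a WT and a K36M background. K36M is the genotype as labelled; replacement of lysine by methionine at that position of histone H3 is known to inhibit the enzymes that methylate it. At d4 and d8 there were 2 libraries per genotype, and at d0 and in iPSCs 1 library per genotype. The series is about how H3K36 methylation maintains cell identity, and its design implies comparisons of K36M with WT at each stage and of d4 with d8 within each genotype. Libraries held 140609320 to 183776429 reads summed over CpGs, with a median coverage of 32 to 44 reads per CpG. Between 2625299 and 2846164 CpGs per library had at least 10 reads, and 2411565 had them in all 12 libraries.

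Mean CpG methylation was lower in K36M than in WT cells at d4 and, by more, at d8. Over the 2411565 common CpGs it was 46.2% ± 0.0362 (SD, n = 2) in K36M against 47.9% ± 0.583 (SD, n = 2) in WT at d4, and 41.1% ± 0.445 (SD, n = 2) against 47.0% ± 0.173 (SD, n = 2) at d8. The difference was -1.73 percentage points at d4 and -5.81 at d8, and both K36M libraries lay below both WT libraries on each day. The MEFs before reprogramming had 47.5% in K36M and 48.5% in WT, and the iPSCs after it 45.6% and 45.9%. Averaged over d4 and d8 the difference was -3.77 points (exact two-sided permutation test within days, p = 0.0556). That is the smallest p the 36 arrangements of these 8 libraries allow, so this design cannot pass 0.05. With reads pooled over CpGs, which weights CpGs by their depth, the difference was -3.89 points with an exact permutation p of 0.111. It was then -1.07 points at d4 and -6.71 at d8. The genotypes then overlapped at d4, with K36M replicate 1 at 43.7% and WT replicate 1 at 43.1%.

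**Figure D1:**
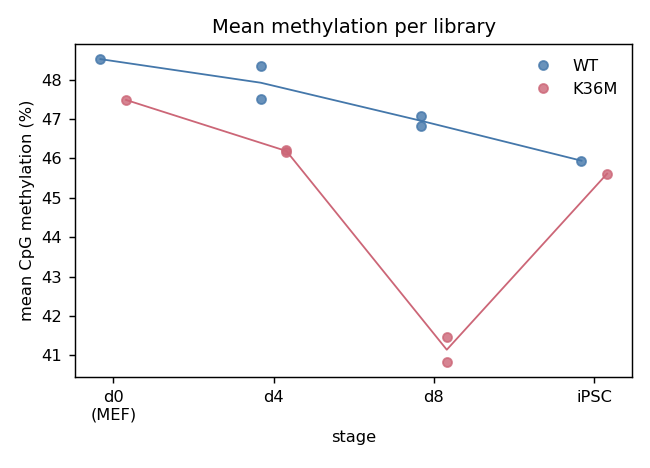
Mean methylation (%) of the 2411565 CpGs with at least 10 reads in all 12 libraries, by stage, with 1 point per library and lines through the genotype means. At d8 the K36M libraries lie near 41.1% and the WT libraries near 47.0%, while the genotypes lie within 1.04 points of each other at d0 and within 0.329 points in iPSCs.

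At d8, methylation was lower in K36M cells across much of the measured genome. Of 227787 tiles of 1 kb, 79357 were lower and 1552 higher in K36M (edgeR quasi-likelihood test, adjusted p under 0.05 and a difference of at least 10 points), with a median difference of -7.04 points over all tiles. Among tiles measured in all 12 libraries, 44.7% of gene body tiles fell in K36M, against 31.9% of intergenic tiles and 22.0% of promoter tiles. Gene bodies averaged 62.8% in K36M and 73.1% in WT, a difference of -10.3 points. Intergenic tiles differed by -8.01 points and promoter tiles, which averaged 28.4% in WT, by -5.0 points. Among tiles over 80% in WT MEFs the order was another, with -12.9 points in promoter, -11.3 in gene body and -8.57 in intergenic tiles. Relative to the WT level promoter tiles lost 17.6%, gene body tiles 14.0% and intergenic tiles 10.99%. Chromosome X, of which 22.2% of tiles fell, differed by -6.17 points and autosomes by -8.40 points. Tiles under 20% in WT MEFs differed by -0.109 points, and 1.16% of them fell while 1.30% rose. Tiles over 80% in WT MEFs differed by -10.1 points and those between 20% and 80% by -9.34 points. CpG-dense tiles with 30 or more measured CpGs, which averaged 13.7% in WT, differed by -1.42 points. Those with 10 to 29 differed by -7.10 points and those with 3 to 9 by -9.21 points. Relative to the WT level these classes lost 10.3%, 12.8% and 12.8%, in the same order. Each of these class differences, averaged over d4 and d8, had an exact permutation p of 0.0556, the smallest the design allows. When limma was run on log ratios centred to one median per library, which removes the general shift of -0.81 (log2) at d8, 17988 tiles were called lower and 1784 higher by at least 10 uncentred points; 17988 and 1545 of these were also edgeR calls of the same direction.

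**Figure D2:**
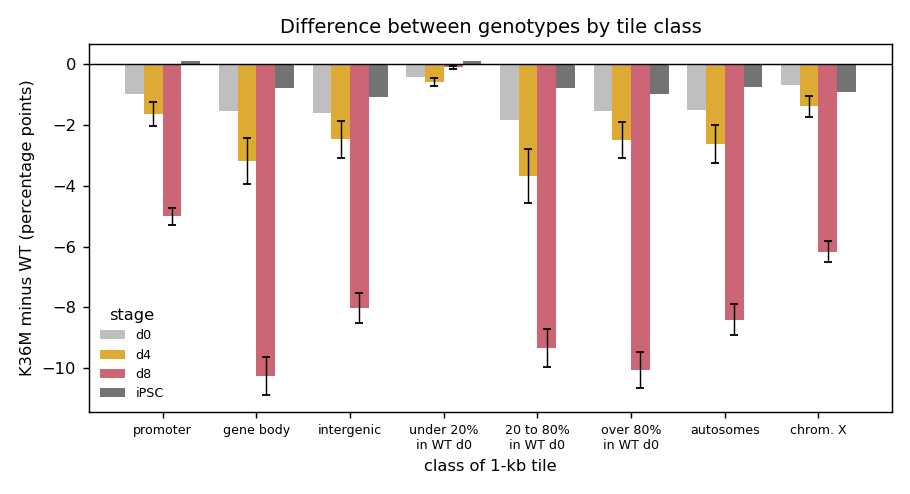
Difference in mean methylation between K36M and WT (percentage points) for classes of 1-kb tiles at d0, d4, d8 and in iPSCs. Bars start at 0 and error bars at d4 and d8 give the pooled SD of the 2 libraries per genotype, while d0 and iPSCs have 1 library per genotype. At d8 gene body tiles reach -10.3 points and tiles under 20% in WT MEFs stay at -0.109 points.

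At d4, losses of the same direction were fewer. In K36M, 8717 tiles were lower and 382 higher than in WT (edgeR, same call), with a median difference of -1.75 points. Gene body tiles differed by -3.18 points, intergenic tiles by -2.48, promoter tiles by -1.65 and chromosome X by -1.39. Of 8643 tiles lower at d4 that were measured in all 12 libraries, 6997 were also lower at d8, where 3017 would be shared by independent lists of these sizes; d4 and d8 share no library. Of 371 tiles higher at d4, 152 were also higher at d8, against 2.5 for independent lists. Those expected counts treat all tiles as equally able to be called. Of tiles under 20% in WT MEFs, only 0.408% and 1.16% were lower at d4 and d8. The labels do not say whether the d4 and d8 libraries came from separate lines. The excess is therefore no independent replication. Among the tiles lower at d4, 39.7% were already at least 10 points lower in the K36M MEF library than in the WT MEF library, against 5.58% of all tiles. The number called at d4 rested on single libraries: it was 1641 without WT d4 replicate 2, 3507 without K36M d4 replicate 1 and 3970 without K36M d4 replicate 2, compared with 9099 with all libraries. limma on log ratios called 1 tile at d4, with 43867 at an unadjusted p under 0.05 against 48370 by edgeR.

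**Figure D3:**
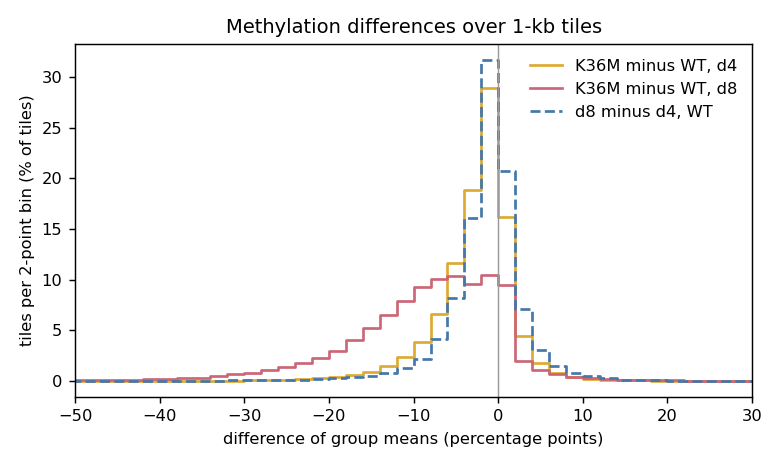
Distribution of the difference in methylation over 227787 tiles of 1 kb, in percentage points, as the percent of tiles per 2-point bin. The K36M minus WT differences have medians of -1.75 points at d4 and -7.04 points at d8, and the change from d4 to d8 within WT has a median of -0.76 points.

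From d4 to d8, 64179 tiles fell and 2437 rose in K36M cells, whereas 4523 fell and 695 rose in WT cells (edgeR). The median change was -5.74 points in K36M and -0.76 points in WT. The test of the difference itself, the genotype by day interaction, called 31252 tiles with a larger fall in K36M and 938 with a smaller fall or a rise. Among tiles measured in all 12 libraries, the fall was larger in K36M in 17.2% of gene body tiles, 12.7% of intergenic tiles, 9.87% of promoter tiles and 10.4% of tiles on chromosome X. In WT cells the count of 5218 became 2140 without WT d4 replicate 2 and 3052 without WT d8 replicate 2, and the interaction count of 32190 became 19499 without WT d4 replicate 1, 20967 without K36M d4 replicate 1 and 20984 without K36M d8 replicate 2. limma called 0 tiles in WT (29868 at an unadjusted p under 0.05, against 32840 by edgeR) and 11335 for the interaction. After centring each library it gave 16903 lower and 2792 higher in K36M, and 216 negative and 272 positive for the interaction.

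Tiles that lose methylation between MEFs and iPSCs were lower in K36M intermediates than in WT intermediates. The 14811 tiles at least 30 points lower in the WT iPSC library than in the WT MEF library averaged 80.5% in WT MEFs, 77.0% ± 1.53 (SD, n = 2) in WT d4, 72.3% ± 0.382 (SD, n = 2) in WT d8 and 34.3% in WT iPSCs. In K36M cells the same tiles averaged 78.4% in MEFs, 72.5% ± 0.000639 (SD, n = 2) at d4, 53.0% ± 1.47 (SD, n = 2) at d8 and 37.7% in iPSCs. At d8, 87.0% of them were called lower in K36M and 0.0270% higher. The 9575 tiles at least 30 points higher in WT iPSCs averaged 34.5% ± 0.781 (SD, n = 2) in WT d8 and 33.8% ± 0.112 (SD, n = 2) in K36M d8, with 76.3% and 73.3% in the iPSCs, and at d8 15.2% of them were lower and 11.5% higher. The difference averaged over d4 and d8 was -11.9 points for the first class and -1.41 points for the second (exact two-sided permutation tests, both p = 0.0556, the smallest possible; 2 tests). The second value changed sign, to 1.49 points (exact permutation p = 0.333), when the class was restricted to tiles at least 50 points higher in WT iPSCs. With tiles selected on the K36M MEF and iPSC libraries instead, the classes differed by -11.5 and -3.54 points (exact permutation, both p = 0.0556). The size of the second value thus depends on which genotype selected the tiles.

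**Figure D4:**
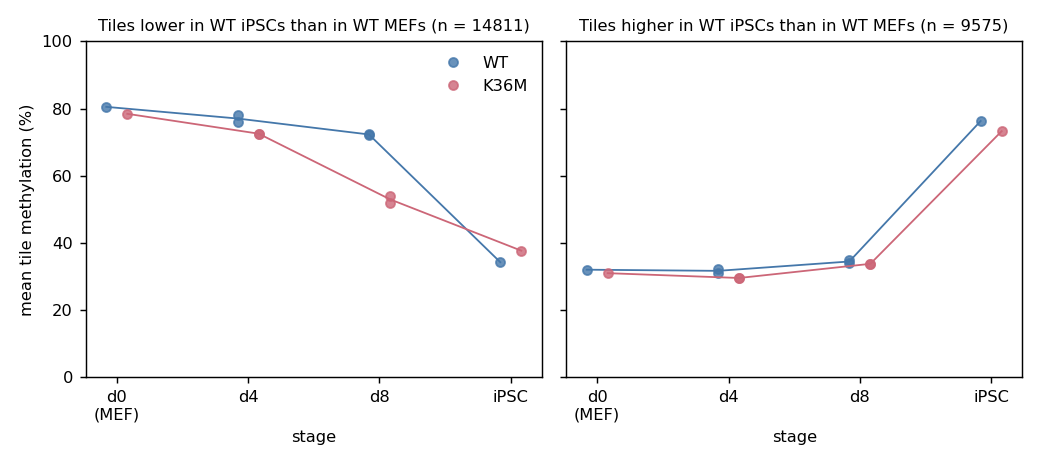
Mean methylation (%) per library over the 14811 tiles lower and the 9575 tiles higher by at least 30 points in the WT iPSC library than in the WT MEF library, by stage, with lines through the genotype means. In the first class K36M d8 lies at 53.0% and WT d8 at 72.3%, and in the second class at 33.8% and 34.5%. The WT d0 and WT iPSC points selected the tiles.

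At d8, promoters of pluripotency, germline and epithelial genes were among those that lost methylation in K36M cells, as were some of genes of other cell types (5 of 12 blood, 6 of 18 endothelial and 4 of 17 muscle promoters). Of 18544 promoters, taken as 1 kb either side of a transcription start, 1909 fell and 26 rose (edgeR, adjusted p under 0.05 and at least 10 points). In the pluripotency and early reprogramming list, in which 8 of 18 measured promoters were over 20% in WT, 8 fell, 8 also when adjusted over the list alone, and 0 rose: Pou5f1, Gdf3, Tdgf1, Tcl1, Dppa3, Zfp42, Dppa4 and Dppa2. Pou5f1, which encodes the pluripotency factor Oct4, fell from 54.2% ± 1.43 (SD, n = 2) in WT to 11.3% ± 7.91 (SD, n = 2) in K36M (edgeR adjusted p = 1.92e-10; 17 CpGs, chromosome 17, 35641982 to 35643982, mm9). Dppa4, a chromatin-associated protein of pluripotent cells, fell from 82.2% ± 0.662 to 38.4% ± 3.77 (adjusted p = 1.81e-12; 20 CpGs, chromosome 16, 48282848 to 48284848). Tcl1, a co-activator of Akt kinase, fell from 74.6% ± 0.454 to 32.2% ± 1.40 (adjusted p = 7.13e-10; 4 CpGs, chromosome 12, 106459926 to 106461926). Tdgf1, a co-receptor of Nodal, fell from 31.7% ± 7.79 to 3.97% ± 2.41 (adjusted p = 7.88e-11; 22 CpGs, chromosome 9, 110847662 to 110849662). In the MEF libraries Tdgf1 already measured 46.0% in WT and 20.1% in K36M. In the iPSC libraries these 4 promoters lay between 2.78% and 19.3% in WT and between 3.47% and 18.2% in K36M. Compared with all other promoters, the list ranked lower in K36M with the preset correlation (limma camera, adjusted p = 0.0432), but not with an estimated one (adjusted p = 0.339 with an estimated correlation), nor without WT d4 replicate 2 (adjusted p = 0.0629) or K36M d4 replicate 2 (adjusted p = 0.0602). Its members split, with a mean difference of -15.2 points and a median of -0.578.

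Germline genes were the list with the most promoters called at d8, and with the most over 20% in WT, 17 of 19. Of 19 measured, 12 fell, 12 also when adjusted over the list alone, and 0 rose: Asz1, Sycp3, Ddx4, Stk31, Tdrd1, Sycp1, Hormad1, Tex19.1, Mael, Sycp2, Tuba3a and Slc25a31. Hormad1, a protein of the meiotic chromosome axis, fell from 85.8% ± 0.682 to 61.9% ± 0.0382 (SD, n = 2 each; edgeR adjusted p = 3.92e-10; chromosome 3, 95362599 to 95364599). Tex19.1, expressed in germ and pluripotent cells, fell from 90.9% ± 2.74 to 65.6% ± 5.15 (adjusted p = 1.31e-09), Stk31 from 71.6% ± 9.04 to 38.9% ± 15.4 (adjusted p = 1.93e-05), and Tdrd1, a Tudor-domain protein of the piRNA pathway, from 62.2% ± 3.81 to 45.6% ± 0.279 (adjusted p = 7.08e-05). The list ranked lower than other promoters (camera, adjusted p = 1.97e-05), a call lost with an estimated correlation (adjusted p = 0.159 with an estimated correlation). The list averaged 70.8% in WT d8, against 28.4% for promoter tiles. Its mean difference at d8 was -12.45 points, and promoter tiles over 80% in WT MEFs differed by -12.9. Its lower rank therefore does not by itself show a loss particular to germline promoters. At d4, 0 of the 19 germline promoters were called by edgeR, over all promoters or over the list alone, and Hormad1 then measured 87.3% ± 1.20 in WT and 85.3% ± 0.747 in K36M (adjusted p = 0.569). The list as a whole leaned upward at d4 relative to other promoters (camera, adjusted p = 0.525) although its mean difference was -0.537 points.

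Epithelial genes had promoters lower in K36M on both days. At d8, 6 of 20 fell, 6 also when adjusted over the list alone (Rab25, Marveld2, Krt18, Cldn6, Cldn4 and Krt8), and at d4, 4 of 20, 4 also when adjusted over the list alone (Rab25, Cldn6, Cldn4 and Krt8). Cldn4, a claudin of tight junctions, fell from 30.4% ± 4.80 to 11.4% ± 0.0981 at d4 (edgeR adjusted p = 3.91e-06) and from 25.3% ± 0.682 to 4.36% ± 2.62 at d8 (adjusted p = 1.05e-10; SD, n = 2 each; 27 CpGs, chromosome 5, 135421804 to 135423804). In the MEF libraries Cldn4 already measured 32.7% in WT and 19.2% in K36M and Krt8 53.5% and 41.4%. Cldn6 was also lower in K36M there, while Rab25 measured 70.5% and 75.3%. The list averaged 13.8% and 10.2% in these MEF libraries. Rab25, a small GTPase of epithelial cells, fell from 50.6% ± 0.116 to 19.5% ± 2.15 at d8 (adjusted p = 7.00e-08), and the keratin gene Krt8 from 50.8% ± 2.91 to 32.8% ± 1.15 (adjusted p = 3.94e-04). The list ranked lower than other promoters at d4 (camera, adjusted p = 1.17e-07) and at d8 (adjusted p = 1.28e-05), and both calls were lost with an estimated correlation (adjusted p = 0.289 with an estimated correlation on each day). The d4 calls of Rab25, Krt8 and Cldn6 each ended without WT d4 replicate 2 (adjusted p = 0.215, 0.204 and 0.410) and without K36M d4 replicate 1 (0.0556, 0.237 and 0.0717), and those of Rab25 and Cldn6 also without K36M d4 replicate 2 (0.211 and 0.0941). Within 500 bp of its start Cldn4 differed by -4.03 points at d4 and -3.73 points at d8, short of the 10 points a call needs.

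Promoters of mesenchymal and fibroblast genes and of TGF-beta signalling genes had little methylation on average in both genotypes. Of 16 mesenchymal and 20 TGF-beta promoters, 0 were called by edgeR at d4 or d8, over all promoters or over the list alone, and the lists averaged 2.29% and 0.762% in WT d8. Vim, the intermediate filament gene of mesenchymal cells, measured 0.213% ± 0.0909 in WT and 2.82% ± 1.04 in K36M at d8 (SD, n = 2 each; adjusted p = 1.19e-09), and Pdgfra, a receptor of fibroblasts, 0.769% ± 0.377 and 4.34% ± 0.855 (adjusted p = 2.58e-06), both under the 10 points a call needs. Pdgfra differed by 0.384 points with a coverage minimum of 20 reads or within 500 bp of its start. Col1a2, a chain of type I collagen, went the other way, with 10.5% ± 2.89 and 5.64% ± 1.14 (adjusted p = 0.00330; 0.142 and 0.0822 without WT d8 replicate 1 and K36M d8 replicate 2). Within 500 bp of its start Col1a2 differed by 0.377 points. Thy1 measured 5.13% ± 0.0117 and 3.22% ± 3.15 (adjusted p = 0.255; -4.14 and 0.319 points without K36M d8 replicates 1 and 2). Tgfb2 measured 0.460% ± 0.0733 and 1.15% ± 0.0497 (adjusted p = 2.63e-05). Relative to other promoters, which averaged -2.59 points, the mesenchymal list ranked higher in K36M at d8 (camera, adjusted p = 3.24e-04; adjusted p = 0.159 with an estimated correlation), and did not stand apart at d4 (adjusted p = 0.525), where it leaned upward relative to other promoters with a mean difference of -0.467 points. The TGF-beta list ranked higher at d4 and d8 (camera, adjusted p = 0.0488 and 0.0398, and 0.289 with an estimated correlation on both days). camera compares log ratios, not points, and the median promoter differed by -0.0624 points at d8. Both lists had 0 members over 20% in WT and so had little room to fall. Their higher rank does not by itself show a gain. The TGF-beta call at d4 ended without WT d4 replicate 1, WT d4 replicate 2 or K36M d4 replicate 2 (adjusted p = 0.0532, 0.167 and 0.265), and the call at d8 without WT d4 replicate 2, WT d8 replicate 1 or K36M d8 replicate 2 (0.0629, 0.0566 and 0.0921).

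Promoters of imprinted genes were not called different between the genotypes. Of 18 measured, 13 of them over 20% in WT, 0 were called by edgeR at d4 or d8, over all promoters or over the list alone, and the list averaged 30.3% in WT d8 and 29.6% in K36M d8. Peg3 measured 40.2% ± 3.15 and 33.3% ± 11.7 at d8 (SD, n = 2 each; adjusted p = 0.229; 0.0138 without K36M d8 replicate 2, where the difference was -15.2 points, against 1.26 points without K36M d8 replicate 1), Impact 43.1% ± 2.21 and 41.6% ± 2.80, Peg10, whose window also covers the start of Sgce, 41.3% ± 0.453 and 37.4% ± 2.43, and H19 56.8% ± 0.187 and 59.9% ± 0.825. Impact differed by 0.438 and Peg10 by -2.20 points without K36M d8 replicate 2, and H19 by -3.05 points with a coverage minimum of 5 reads. Among 19 enzymes of DNA and H3K36 methylation, 1 promoter fell at d8, also when adjusted over the list alone, and 0 at d4: Dnmt3l, a cofactor of the de novo methyltransferases, from 50.6% ± 1.95 to 35.2% ± 1.17 (edgeR adjusted p = 4.10e-04), in a window shared with the promoter of Aire. Tet1, which oxidises methylcytosine, measured 89.7% ± 0.129 in WT and 80.1% ± 0.693 in K36M at d8 (adjusted p = 4.82e-04), a difference of -9.66 points, and -10.2 points without K36M d8 replicate 1. Of 19 Hox promoters 0 were called on either day, over all promoters or over the list alone; Hoxc4 measured 11.1% ± 1.32 in WT and 6.13% ± 0.393 in K36M at d4 (adjusted p = 0.00821). The Hox list ranked lower than other promoters at d4 (camera, adjusted p = 0.0398; adjusted p = 0.289 with an estimated correlation), but not without WT d4 replicate 2 (0.258) or K36M d4 replicate 2 (0.265). At d8 the Hox list (camera, adjusted p = 0.410) and on both days the imprinted list (0.109 and 0.352) leaned upward relative to other promoters although their mean and median differences were negative, and the enzyme list did not stand apart (0.848 and 0.635).

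The largest losses at d8 lay at promoters outside these lists. Ninj2, an adhesion protein, fell from 67.4% ± 5.56 to 14.1% ± 7.91 (SD, n = 2 each; edgeR adjusted p = 4.23e-10; 4 CpGs, chromosome 6, 120142841 to 120144841). Zmynd8, a reader of chromatin marks, fell from 73.3% ± 3.35 to 26.0% ± 5.43 (adjusted p = 1.81e-12; 25 CpGs, chromosome 2, 165721450 to 165723450), and Trap1a, an X-linked tumour antigen, from 94.1% ± 0.137 to 48.5% ± 1.67 (adjusted p = 1.58e-10). Casp14, a caspase of the epidermis, fell from 63.5% ± 3.16 to 17.5% ± 7.53 (adjusted p = 4.71e-09). The other 6 of the 10 largest losses (Gm14635, Gm17440, Gm13227, Gm13049, A630001G21Rik and Gm16137) ranged from -53.4 points for Gm14635 to -46.3 for Gm16137. The largest gains were smaller: 2610028E06Rik rose from 20.03% ± 5.79 to 39.9% ± 1.63 (adjusted p = 1.24e-04; 4 CpGs) and Gm16151 from 27.5% ± 1.83 to 47.1% ± 2.97 (adjusted p = 4.95e-04; 3 CpGs), followed by A330070K13Rik, Gm15941 and Gm10304. Those 5 promoters lay between 83.0% and 91.0% in WT iPSCs. Without K36M d8 replicate 1 the call of Gm10304 ended (adjusted p = 0.0813).

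At d4, 196 promoters fell and 8 rose in K36M (edgeR). The largest loss was at Tdgf1, from 40.4% ± 7.67 to 10.7% ± 0.264 (SD, n = 2 each; edgeR adjusted p = 1.78e-07), which in the MEF libraries already measured 46.0% in WT and 20.1% in K36M. Slc5a4a fell from 60.1% ± 9.46 to 31.9% ± 0.698 (adjusted p = 6.70e-06), with 73.1% and 69.4% in MEFs; within 500 bp of its start it differed by -8.66 points (adjusted p = 0.294). Zfp750, a factor of epidermal differentiation, fell from 44.5% ± 9.34 to 16.5% ± 1.73 (adjusted p = 3.08e-06), and Guca1b, a retinal regulator of guanylate cyclase, from 57.1% ± 6.25 to 31.3% ± 0.0824 (adjusted p = 2.18e-04), with 65.4% and 33.5% in MEFs. Mst1, whose window also covers the start of Rnf123, fell from 68.6% ± 5.94 to 43.1% ± 0.226 (adjusted p = 1.74e-04). The other 5 of the 10 largest losses (Fam25c, C030013C21Rik, 1600029D21Rik, Gm12409 and Tmem59l) ranged from -27.5 points for Fam25c to -24.9 for Tmem59l. In MEFs C030013C21Rik (58.9% in WT and 35.0% in K36M), Gm12409 (59.5% and 33.3%) and Tmem59l (55.4% and 28.9%) already differed by about as much. Zfp750 (57% and 47.0%) and Mst1 (79.7% and 72.8%) differed by less there. Fam25c (72.6% and 72.2%) and 1600029D21Rik (83.65% and 83.85%) were close. Of the 10, only Guca1b kept a gap of that size in iPSCs (46.35% in WT and 17.82% in K36M). Of the pluripotency list 2 of 18 fell at d4 (Tdgf1 and Zfp42), and 3 when adjusted over the list alone, with Pou5f1 as the third. Pou5f1 measured 49.0% ± 7.60 in WT and 37.6% ± 0.574 in K36M at d4 (adjusted p = 0.186), and 0.01002 and 0.00663 with coverage minimums of 5 and 20 reads. Without WT d4 replicate 2 it differed by -6.03 points (adjusted p = 0.819). The list ranked lower than other promoters at d4 (camera, adjusted p = 0.0182; adjusted p = 0.289 with an estimated correlation), though not without WT d4 replicate 2 (0.0856).

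Gains at d4 were led by 5430427M07Rik, which rose from 45.9% ± 2.43 to 67.2% ± 2.06 (SD, n = 2 each; edgeR adjusted p = 6.00e-04), and Gm6724, which rose from 71.6% ± 2.22 to 91.2% ± 0.218 (adjusted p = 0.00145) and at d8 was lower in K36M, at 64.6% ± 11.8 against 83.6% ± 10.4 (adjusted p = 0.00358). Eif2s3y, a Y-linked subunit of a translation initiation factor, rose from 8.29% ± 5.29 to 24.1% ± 2.77 at d4 (adjusted p = 4.78e-04) and from 2.83% ± 1.57 to 15.3% ± 2.14 at d8 (adjusted p = 1.71e-05), and measured 3.52% in WT and 29.03% in K36M MEFs. Srpx2 and 3110070M22Rik completed the 5 largest gains. All 5 promoters were already higher in the K36M than in the WT MEF library. In WT and K36M MEFs Gm6724 measured 64.8% and 92.3%, a wider gap than at d4. There 5430427M07Rik measured 45.48% and 57.05%, 3110070M22Rik 56.6% and 72.5%, and Srpx2 23.9% and 33.0%. Promoter calls at d4 rested on single libraries: the total of 204 became 44 without WT d4 replicate 2, 90 without K36M d4 replicate 1 and 106 without K36M d4 replicate 2. Without WT d4 replicate 2 the calls of Fam25c, 1600029D21Rik, Gm12409, Srpx2 and Eif2s3y ended (adjusted p = 0.0943, 0.333, 0.0608, 0.514 and 0.107), without K36M d4 replicate 1 those of Gm6724 and Srpx2 (0.0556 and 0.229), and without K36M d4 replicate 2 those of 1600029D21Rik and Srpx2 (0.0608 and 0.186). The call of Srpx2 also ended with a coverage minimum of 5 reads (0.214) and within 500 bp of its start (0.141). limma called 0 promoters at d4, with 2475 at an unadjusted p under 0.05 against 2879 by edgeR.

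**Figure D5:**
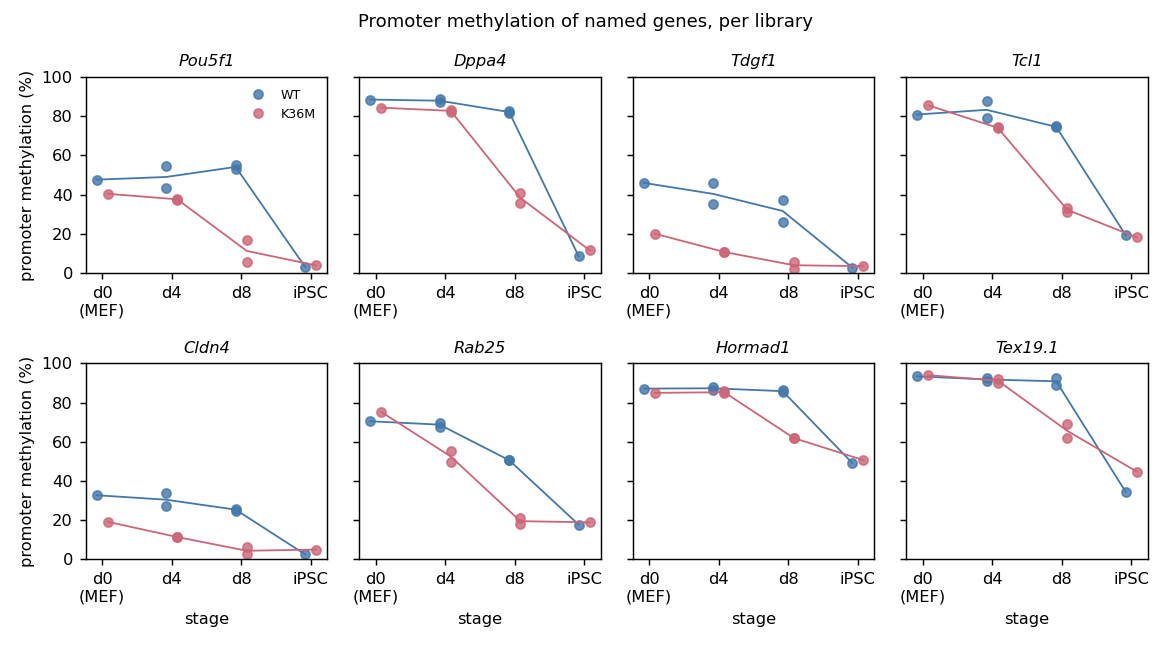
Promoter methylation (%) per library by stage for Pou5f1, Dppa4, Tdgf1, Tcl1, Cldn4, Rab25, Hormad1 and Tex19.1, with 1 point per library and lines through the genotype means. All 8 promoters are lower in both K36M d8 libraries than in both WT d8 libraries. The same holds at d4 except for Tex19.1, and at d0, with 1 library each, except for Tcl1, Rab25 and Tex19.1.

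Trophoblast genes lost promoter methylation in part. Of 16 measured, 4 fell at d8 (Krt7, Gcm1, Elf5 and Hand1), 4 also when adjusted over the list alone, and 2 at d4 (Elf5 and Hand1), 2 also when adjusted over the list alone. Hand1, a transcription factor of trophoblast and heart, fell from 31.8% ± 8.43 to 15.2% ± 0.764 at d4 and from 35.7% ± 1.68 to 10.0% ± 3.40 at d8 (SD, n = 2 each; edgeR adjusted p = 1.24e-04 and 9.97e-10). Its d4 difference was -10.65 points without WT d4 replicate 2, against -16.6. Hand1 was already lower in the K36M than in the WT MEF library. Elf5, a trophoblast factor, fell from 50.2% ± 0.478 to 26.5% ± 4.82 at d8 (adjusted p = 2.39e-06); its d4 call ended without WT d4 replicate 2, K36M d4 replicate 1 or K36M d4 replicate 2 (adjusted p = 0.635, 0.232 and 0.206) with a coverage minimum of 20 reads (0.622) and within 500 bp of its start (0.0591). With that coverage minimum Elf5 differed by -10.2 points at d8, against -23.7. The list did not stand apart from other promoters (camera, adjusted p = 0.109 at d4 and 0.615 at d8).

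Lists of other cell types that such cultures could hold were also lower at some promoters. Of 12 blood promoters 5 fell at d8 (Sfpi1, Laptm5, Gata1, Vav1 and Cd79b), 5 also when adjusted over the list alone. Gata1, an erythroid factor on chromosome X, fell from 88.4% ± 2.61 to 55.4% ± 0.303 (SD, n = 2 each; edgeR adjusted p = 1.73e-06) and Laptm5, a lysosomal protein of blood cells, from 65.2% ± 1.40 to 34.1% ± 6.21 (adjusted p = 8.45e-08; -16.6 points within 500 bp of its start, against -31.1). Of 18 endothelial promoters 6 fell at d8 (Tek, Pecam1, Eng, Nos3, Tie1 and Mmrn2), 6 also when adjusted over the list alone; Pecam1, an endothelial adhesion molecule, fell from 85.7% ± 2.67 to 57.0% ± 6.83 (adjusted p = 1.22e-07; -11.7 points with a coverage minimum of 20 reads, against -28.7). Of 17 muscle promoters 4 fell at d8 (Myog, Chrna1, Mylpf and Cav3), 4 also when adjusted over the list alone; Myog, a factor of muscle differentiation, fell from 84.6% ± 1.04 to 62.7% ± 4.13 (adjusted p = 3.14e-08). Of 18 neural promoters 0 were called by edgeR on either day, over all promoters or over the list alone; Sox10, a neural crest factor whose window also covers the start of Gm10863, measured 2.33% ± 0.0693 and 5.79% ± 0.218 at d8 (adjusted p = 8.60e-07; a difference of 1.02 points, adjusted p = 0.621, within 500 bp of its start). Syp had a lower value in K36M, with 35.2% ± 3.11 and 27.6% ± 1.58 (adjusted p = 0.0435, and 0.260 and 0.233 without WT d8 replicate 2 and K36M d8 replicate 2). So did Gfap, with 77.8% ± 2.53 and 72.8% ± 5.60 (adjusted p = 0.251). Its difference was -8.93 and -1.01 points without K36M d8 replicates 1 and 2. For Syp the difference was 1.68 points with a coverage minimum of 5 reads and 1.10 within 500 bp of its start. At d8 the neural list ranked higher than other promoters (camera, adjusted p = 0.00158, and 0.159 with an estimated correlation). With 2 of its 18 members over 20% in WT, it had little room to fall. The blood, endothelial and muscle lists did not stand apart (camera, adjusted p = 0.139, 0.109 and 0.301).

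At d4, 1 endothelial promoter fell, also when adjusted over the list alone: Eng, an endothelial TGF-beta co-receptor, from 50.9% ± 2.05 to 40.4% ± 3.20 (SD, n = 2 each; edgeR adjusted p = 0.0468). That call ended without any single d4 library: adjusted p = 0.0745 and 0.428 without WT d4 replicates 1 and 2, and 0.103 and 0.400 without K36M d4 replicates 1 and 2. Of the blood and muscle lists 0 promoters were called at d4 and 1 each when adjusted over the list alone (Laptm5 and Cav3). The endothelial and muscle lists ranked lower than other promoters at d4 (camera, adjusted p = 0.0398 and 0.0182; adjusted p = 0.289 with an estimated correlation for both). The blood (0.170) and neural (0.782) lists did not stand apart. The endothelial call ended without WT d4 replicate 2, K36M d4 replicate 1 or K36M d4 replicate 2 (0.155, 0.0917 and 0.0602), and the muscle call without WT d4 replicate 2 or K36M d4 replicate 2 (0.0629 and 0.0616).

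MEFs and iPSCs had 1 library per genotype, so their differences have no replicate check. In MEFs, the difference of mean methylation (K36M minus WT) was -1.04 points (95% counting interval -1.04 to -1.03), and 0.662% of 223636 tiles differed by at least 20 points, 0.564% lower and 0.0975% higher in K36M. In iPSCs the difference was -0.329 points (95% counting interval -0.337 to -0.321), and 0.195% of tiles differed by at least 20 points. Between replicate libraries at d4 and d8, 0.123% to 0.391% of tiles differed by as much, while 17.9% did between WT MEFs and WT iPSCs and 17.4% between K36M MEFs and K36M iPSCs. The 78064 tiles lower at d8 averaged 69.2% in WT iPSCs and 68.9% in K36M iPSCs, and 93.8% of them lay within 10 points of each other there, against 95.7% of all tiles and 96.7% of tiles not called at d8. In MEFs, Tdgf1 (46.0% in WT, 20.1% in K36M), Cldn6 (29.5% and 4.55%) and Hand1 (41.1% and 20.2%) were lower in the K36M library, while Dppa4 measured 88.6% and 84.4% and Tcl1 80.9% and 85.6%.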

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

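Of the tests on the loss at d8, those on mitochondrial reads and on tiles higher in WT iPSCs were chosen only after the result was seen. The difference between K36M and WT differed between d4 and d8 in 32190 tiles and in 895 promoters, by the genotype by day interaction of edgeR. The tile count was 19499 without WT d4 replicate 1, 20967 without K36M d4 replicate 1, 20984 without K36M d8 replicate 2 and 11335 by limma, and 488 by limma after centring each library, with 216 negative and 272 positive. The promoter count was 487, 512 and 463 without those libraries and 1 by limma (4293 at an unadjusted p under 0.05, against 5044 by edgeR). After centring each library limma called 660 promoters, 659 of them negative, of which 617 were also negative calls of edgeR. For promoters, unlike tiles, centring does not remove a general loss at d8. The K36M minus WT median log ratio of promoters was -0.194 (log2) at d4 and 0.141 at d8. Centring therefore moves the promoter interaction towards loss and is no stricter test of it. Among named promoters Pou5f1 (adjusted p = 5.08e-05), Dppa4 (6.99e-06) and Hormad1 (5.11e-05) passed this test, while Tdgf1 did not (0.0821).

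The loss at d8 was weighed against incomplete or excessive conversion and against a mixture of cells. Mitochondrial CpGs, which should be nearly unmethylated, differed by -0.0313 points between WT and K36M d8 (WT minus K36M), so unconverted cytosines in WT cannot account for the loss. A uniform loss in the K36M libraries would leave 0.60% of the tiles over 80% in WT d8 with a loss under 3 points, but 14.2% of 58531 had one. Admixed iPSC-like cells alone would leave tiles unchanged that are over 80% in MEFs and iPSCs. Yet 42230 such tiles had a median difference of -6.52 points (pairs of libraries -7.07 to -5.98). The tiles higher in WT iPSCs differed by -0.696 points, where 21.2 were needed if such cells made the whole loss. Neither value can exclude such cells beside a general loss, which could mask gains. Of the tiles higher in WT iPSCs 11.5% were called higher and 15.2% lower at d8, against 0.681% and 34.9% of all tiles. Those selected at 50 points differed by 3.51 points at d8, and those selected on the K36M MEF and iPSC libraries by -2.77. A loss in the K36M cells themselves is a candidate explanation that remains open. iPSC-like cells as a part of the loss also remain open, as does a larger share of an intermediate cell state. Such a state may differ from both MEFs and iPSCs and was not tested.

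Mitochondrial CpGs, which the comparisons do not use, had a methylated share of at most 0.358% (WT d0, 89565 reads), above the 0.00335% that a count of 0 would allow there; the lowest was 0.281% (WT iPSC).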

How the results depend on the processing

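The alternatives with edgeR dispersion 0 and with all gene types were chosen only after the results were seen; the others were planned, and the cause of each change was not tested unless the setting itself shows it. Of 2419 alternatives for named promoters, 2251 kept direction and side of the threshold, 104 lost a call, 33 gained one and 31 changed sign, 0 of them for a called difference. Of 286 for list tests 252 kept both, 28 lost a call, 1 gained one and 5 changed direction with no call. Of 60 for tile classes 55 stayed within the spread. Dispersion 0 gave 9677 tiles at d4 and 81103 at d8, and all gene types 240 promoters at d4 and 2747 at d8. At a median of 308 reads per tile, simulated changes of 10 points were called in 19 of 100 tiles and passed the adjusted p alone in 27; the part of depth in this was not separated from that of replicate spread.

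With all 4 stages permuted, mean methylation differed by -2.23 points (exact permutation p = 0.0139, the smallest possible there), tiles lower in WT iPSCs by -5.62 (p = 0.0972, exact) and tiles higher in WT iPSCs by -1.72 (p = 0.0139, exact). WT d0 and WT iPSC selected the tiles of both classes, so these 2 values are no test of them. That second class, selected at 50 points, differed by 1.49 points in the opposite direction. Calls at 20 points left 1414 tiles at d4, 21756 at d8, 1218 for WT d8 against d4, 17730 for K36M d8 against d4 and 9633 for the interaction, and 22 and 614 promoters at d4 and d8. The adjusted p alone gave 15842, 128940 and 108818 tiles at d4, at d8 and for K36M d8 against d4, and 819 and 6349 promoters, the last with 71.8% lower. At least 5 CpGs per tile, which tests fewer tiles, gave 5529, 46471, 3170 and 39494 tiles at d4, at d8 and for d8 against d4 in WT and in K36M.

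limma on log ratios gave 1 tile at d4, 0 for WT d8 against d4 (29868 at an unadjusted p under 0.05), 11335 for the interaction and 0 promoters at d4 (2475). With centring it gave 1 tile at d4, 19772 at d8, 0 for WT (26744), 19695 for K36M, 488 for the interaction and 0 promoters at d4 (1918). Lists past 0.05 with camera, 12 of 26, became 0 with an estimated correlation and 0 by exact permutation of list means, which cannot pass 0.05. Leaving out single libraries, which leaves a lone library assumed to vary like the others, gave 1641 to 12057 tiles at d4, 69938 to 82040 at d8, 2140 to 5338 for WT, 56374 to 67350 for K36M and 19499 to 32164 for the interaction, 44 to 250 promoters at d4 and 1675 to 1974 at d8, and 5 to 12 lists, 5 without WT d4 replicate 2.

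For MEFs the mean difference was -1.07, -0.998 and -1.08 points, and for iPSCs -0.369, -0.298 and -0.239, with coverage minimums of 5 and 20 reads and pooled reads. The share of tiles that differ was 0.0778% in MEFs and 0.0157% in iPSCs at 30 points, 0.901% and 0.370% at 5 reads, and 0.512% and 0.0905% at 20 reads. At d8, tiles with 10 to 29 CpGs differed by -6.40 points at 20 reads, those with 30 or more by -1.56 and -1.04 at 5 and 20 reads, and promoter tiles by -5.29 and -4.47.

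Replicate numbers do not pair these libraries. A fit with the replicate block gave 8397 tiles at d4, 80621 at d8, 4865 for WT, 66201 for K36M and 30333 for the interaction, 192 and 1934 promoters, and 12 lists; it ended 3 calls among named promoters at d4 (Srpx2, Elf5 and Eng) and 0 at d8.

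Sign changes all concerned differences under 10 points, with a largest size of 5.95 points under the alternative. Within 500 bp of the start they were Col1a2 at d8 (0.377 points), Pdgfra at d4 (0.00552, as also with 20 reads), Thy1 at d8 (0.637), H19 at d8 (-2.23), Kdm4a at d8 (0.00172) and Syp at d8 (1.10). With 5 reads they were H19 at d8 (-3.05), Kdm4a at d4 (-0.0904) and Syp at d8 (1.68), and with 20 reads Tex19.1 at d4 (0.0716). Leaving out single libraries gave ranges at d4 of -0.129 to 2.22 points for Stk31, -1.65 to 0.381 for Tex19.1, -0.325 to 0.206 for Pdgfra, -0.756 to 1.05 for Tgfbi, -8.32 to 5.95 for Peg3, -1.85 to 0.209 for Peg10, -0.278 to 1.10 for Kdm4a, -1.61 to 0.387 for Tdg, -4.84 to 2.21 for Gcm1, -2.90 to 1.25 for Sfpi1 and -4.53 to 0.107 for Nos3, and at d8 of -4.14 to 0.319 for Thy1, -3.52 to 0.438 for Impact and -15.2 to 1.26 for Peg3. Lists that changed direction at d4 were the mesenchymal one (camera, adjusted p = 0.767 with 5 reads, 0.295 to 0.998 without single libraries), the neural one (0.312 to 0.938) and the enzymes (0.45 to 0.927).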

Other observations

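The test on the larger loss in gene bodies and that on iPSCs were both written before their results were seen. The loss in K36M at d8 also reached regions whose methylation MEFs and iPSCs share. Of 147772 tiles within 10 points of each other in WT MEFs and WT iPSCs, 27.6% were lower in K36M at d8 and 0.0826% higher. The 21073 tiles lower by at least 20 points averaged 77.6% in WT MEFs, 72.2% in WT d8, 45.5% in K36M d8, 60.1% in WT iPSCs and 60.6% in K36M iPSCs. The 1522 tiles higher in K36M at d8 averaged 29.6% in WT d8, 44.7% in K36M d8 and 77.5% in WT iPSCs.

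Gene body tiles lost more than intergenic tiles at d8, by -2.24 points, and gene bodies differ from intergenic regions in CpG number, methylation level and depth. After matching 81148 tiles on these, the gap was -2.17 points (-2.36 to -1.98 over the 4 pairs of libraries), so these properties do not account for it. The matched gap was 0.109 points at d0, -0.633 at d4 and 0.300 in iPSCs. Promoter tiles over 80% in WT MEFs lost more than either (-12.9 points, against -11.3 in gene body and -8.57 in intergenic tiles of that level). That comparison was not matched, and tiles near a start can lie inside a gene. It therefore cannot decide whether the loss is specific to gene bodies. Transcription and H3K36 methylation were not analysed here.

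Whether iPSCs keep part of the loss was tested on tiles lower by at least 20 points at d8. In K36M minus WT iPSCs they differed from level-matched uncalled tiles by 0.335 points (0.567 for all such tiles and -0.981 for all uncalled tiles). The data therefore do not show a retained loss. With 1 iPSC library per genotype, a difference between lines could not be separated from the genotype. The iPSCs had also been passaged in S/L without doxycycline, while the intermediates were in AGi medium. Whether K36M still acted in the iPSCs was not analysed here.

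Tiles lower in K36M at d4 were lower in WT d4 replicate 1 than in replicate 2 by at least 10 points in 17.0% of cases, against 2.91% of all tiles. The same WT d4 libraries entered the call, so part of this excess can follow from the selection. In MEFs the tiles lower at d4 averaged 64.5% in WT and 55.9% in K36M, and in iPSCs 58.5% in both.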
